A study of Arabidopsis thaliana with 10 samples.

How the data were processed

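The data are 10 Affymetrix ATH1 arrays of whole Arabidopsis thaliana plants in 5 groups of 2: control plants at 2 and 4 days, boron-deficient plants at 2 and 4 days and calcium-deficient plants at 2 days. Per the labels, replicates are biological, plants grew on perlite with 25 µM boron and 3 mM calcium, and treatment meant a change to a solution without boron or without calcium. The labels place the start of the treatment differently in the protocol and in the design text, so only the ages at sampling, 19 and 21 days, are given. Per the labels, total RNA was extracted on spin columns and biotin-labelled RNA was hybridized. The deposited values are probe set signal intensities on a linear scale, made with GCOS 1.4 per the submitters' processing notes. The scaling target and any later normalization are not given in the sources used here.

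The deposited table holds 22746 probe sets. Its 6 arrays of 2 days have median signals of 114.884 to 121.212 and a lowest value of 0. Its 4 arrays of 4 days have medians of 231.564 to 243.414 and a lowest value of 1, so they were scaled apart from the others. The log2 medians ran from 7.03 to 8.02, a gap over the limit of 0.5 set in advance, and by that rule the arrays were quantile normalized together. Values were then taken as log2(signal + 16), and probe sets with a mean under the 25th percentile were left out, which kept 17059 and left out 5687. For arrays, their number limits the precision: n = 2 per group.

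Groups were compared with limma 3.58.1 in R 4.3.3, with a mean for each of the 5 groups, contrasts of these means, 5 residual degrees of freedom, moderated tests with an intensity trend, and Benjamini-Hochberg adjustment over the 17059 probe sets at 0.05. Standard errors and 95% confidence intervals come from the same moderated fit. The contrasts were boron deficiency against control at 2 and at 4 days, calcium deficiency against control at 2 days, boron against calcium deficiency at 2 days, the difference of the boron responses at 4 and 2 days, and control plants at 4 against 2 days. Sampling day and processing of the arrays go together, so the last contrast mixes them. The difference of the boron responses compares differences within each day, and processing that alters the size or spread of changes may not cancel in it. The other contrasts compare arrays of the same day. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

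Gene names came from the name table, which lists 14016 of the probe sets: 13513 with a single gene and 503 with several. Of the single genes 13436 matched a locus of the RefSeq annotation of TAIR10.1 and 77 did not, and 8730 probe sets had no name in the sources used here. After the filter 9460 probe sets with a single gene and 7265 without a name were left. Unnamed probe sets and those with several genes count in the tests and are not named. No genome build is given for the arrays, and coordinates were not used here.

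Gene lists were fixed before the data were examined, as were the groups, contrasts, tests, the rule for named genes and the first set of alternatives. The 26 lists hold 444 entries, of which 76 have a named probe set and 72 pass the filter. For 1 entry the symbol pointed to another locus, which was used. The 12 lists with at least 3 measured genes were tested: degradation and synthesis of branched-chain amino acids, wall loosening, calcium, rapid stress transcription factors, oxidative stress, sugar starvation and darkness, photosynthesis, root markers, auxin, phenylpropanoids, and abscisic acid, cold and dehydration. Each was tested in the 3 deficiency contrasts, 36 tests adjusted together, with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry; the last tests only whether the genes of a list move in 1 direction on balance. Of the 36 camera tests 12 passed, and 0 passed with an estimated correlation, the lowest of whose adjusted p was 0.190. By fry the degradation list passed under boron loss at 2 and 4 days and under calcium loss (adjusted p = 0.00469, 0.0261 and 0.00469). Under calcium loss the synthesis (fry, adjusted p = 0.0106), oxidative stress (0.0106) and photosynthesis (0.0115) lists passed by fry and not by camera. Under boron loss the starvation (fry, adjusted p = 0.227) and rapid stress (0.235) lists at 4 days and the root list at 2 days (0.0863) passed by camera only. Members at an adjusted p of 0.05 were counted over all probe sets and adjusted over the list alone. Where a gene had several probe sets of its own, that with the highest mean signal was used.

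Named genes followed a rule. It took, per deficiency contrast, the 10 most raised and 10 most lowered genes among those past the threshold with both deficient arrays beyond both controls, or the 5 lowest p per direction where fewer than 5 passed. It added up to 4 members of each list past the threshold, or up to 2 as values where none passed. It added BOR1, NIP5;1, BCAT2, IVD, MCCA, BCAT4 and CAX3 in every deficiency contrast, and for the direct and interaction contrasts the 5 largest changes in each direction. This gave 147 gene results, 101 of them past the threshold. ALDH6B2, the genes beyond the rule in the comparisons of controls, of boron against calcium and of interactions, the plastid genes and the members of gene families were named after their values had been seen.

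The other settings chosen beforehand were pseudocounts of 1 and 64, the values as deposited, centring of each array on its median log2 value, no filter, a filter at the 50th percentile, no intensity trend, only the groups compared, the replicate number as a block in 2 versions, a threshold of 2-fold, and leaving out each array in turn. Chosen after seeing the data were fits of the arrays of the same day only (6 or 4 arrays), array weights per group, a block with crossed numbers, 24 sets of at least 8 genes (families that share the stem of their symbol, and the genes encoded in the plastid, adjusted over 72 tests), 17 nuclear photosynthesis genes, and the SD of the log2 changes shared by separate pairs of arrays, from the covariance over probe sets of 2 differences between a deficient and a control array.

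The fit was tested on simulated data, 10 draws of 17059 probe sets with 200 changed in each, with the spread of each real group. Of changes of 1.5-fold, 2-fold and 4-fold it recovered 29.4%, 83.1% and 99.7% for boron at 2 days, 18.5%, 86.2% and 98.9% for boron at 4 days, and 24.6%, 85.4% and 99.1% for calcium. The false share of the calls was 34.6%, 0.456% and 14.6% in that order, and 9.09%, 6.47% and 9.05% where all groups had an equal spread. All 20 of 20 lists of 13 genes shifted by −0.5 were found by each of the 3 list tests, and of 20 lists without a shift camera found 2, camera with an estimated correlation 1 and fry 2. The spread of each real group holds for the 10 draws above, not for these lists. Lists with correlated genes or both directions were not simulated. Of the 13 real degradation genes 4 had a positive log2 change under boron loss at 2 days. Estimated correlations within the real lists ran from −0.21 (oxidative stress) to 0.63 (root markers). The list results therefore cannot be carried over to the real lists.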

Results

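Messenger RNA of whole Arabidopsis thaliana plants was measured on 10 ATH1 arrays. The arrays fall into 5 groups of 2 biological replicates. Control plants and boron-deficient plants were taken after 2 and after 4 days, at ages of 19 and 21 days. Calcium-deficient plants were taken after 2 days only. Before treatment all plants grew on perlite with 25 µM boron and 3 mM calcium. The deposited median signal was 115 to 121 on the arrays of 2 days and 232 to 243 on the arrays of 4 days, so the days had been scaled apart before deposition. Replicate arrays correlated with Spearman coefficients of 0.969 (control 2 d), 0.981 (boron-deficient 2 d), 0.993 (calcium-deficient 2 d), 0.993 (control 4 d) and 0.992 (boron-deficient 4 d). The first principal component held 59.7% of the variance and split the days. With 2 arrays per group, their number limits the precision. Signals given with genes are means ± SD after quantile normalization, n = 2 arrays per group, and log2 changes carry their standard error (SE) and the adjusted p of limma over 17059 probe sets.

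The comparison of boron-deficient with control plants at 2 days asked which transcripts answer early to the loss of boron, and whether those of branched-chain amino acid metabolism, the subject of the study, are among them. Of the transcripts of leucine and valine breakdown 5 fell. IVD (AT3G45300), the isovaleryl-CoA dehydrogenase of leucine breakdown, fell from 2786 ± 681 to 657 ± 165, which is 4.16-fold (log2 change −2.06, SE 0.31, 95% confidence interval −2.75 to −1.36, adjusted p = 0.00669). The carboxylase that acts after it fell with both of its measured subunits: MCCA (AT1G03090) went from 3008 ± 1358 to 725 ± 55.7 (log2 change −1.95, SE 0.28, adjusted p = 0.00527) and MCCB (AT4G34030) from 1770 ± 360 to 711 ± 42.8 (−1.28, SE 0.15, adjusted p = 0.00302). ETFQO (AT2G43400), which passes electrons from such dehydrogenases to ubiquinone, fell by 1.56 on the log2 scale (SE 0.22, adjusted p = 0.00494). ALDH6B2 (AT2G14170), a methylmalonate semialdehyde dehydrogenase of valine breakdown, fell by 1.02 (SE 0.20, adjusted p = 0.0167). Of the 13 measured genes of the degradation list, 5 fell and 0 rose over all probe sets (6 fell and 2 rose adjusted over the list alone), with a median log2 change of −0.26. The list as a set lay lower than the other genes (camera, adjusted p = 0.0122), but not with its correlation estimated from the data (adjusted p = 0.222 with an estimated correlation). The same 5 genes were also lower in control plants of 4 days than in control plants of 2 days, with a median log2 difference of −1.82, and the root marker PYK10 was higher in the boron-deficient plants (log2 change 0.73).

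BCAT4 (AT3G19710), an aminotransferase that starts the chain elongation of methionine for glucosinolates, rose from 755 ± 30.6 to 2379 ± 61.4 (log2 change 1.64, SE 0.21, adjusted p = 0.00392). The glucosyltransferases of glucosinolate synthesis UGT74C1 (AT2G31790; 0.92, adjusted p = 0.00720) and UGT74B1 (AT1G24100; 0.56, adjusted p = 0.0428) rose as well, the latter not with the values as deposited (adjusted p = 0.0879) or median centring (adjusted p = 0.0932). The UGT74C1 call was lost with array weights (adjusted p = 0.0515) and with only the groups compared. The UGT74B1 call was kept in 1 of 10 left-out cases and was also lost without the filter, with either replicate block, with arrays of the same day only (adjusted p = 0.122) and with array weights (adjusted p = 0.202). Among the 5 measured genes of branched-chain amino acid synthesis and its precursors the directions parted. MGL (AT1G64660), a methionine gamma-lyase that supplies isoleucine, fell from 1697 ± 381 to 259 ± 87.8, which is 6.30-fold (log2 change −2.66, SE 0.28, adjusted p = 0.00188), and was also lower in control plants of 4 days than of 2 days (−1.84). AHASS1 (AT2G31810), a regulatory subunit of acetohydroxyacid synthase, fell by 0.87 (adjusted p = 0.0357). Its change ran from −1.14 to −0.60 with each array left out. The call was kept in 2 of 10 cases and lost with either replicate block, with arrays of the same day only and with array weights. DHAD (AT3G23940), dihydroxyacid dehydratase, rose by 0.82 (adjusted p = 0.0192), a call kept in 8 of 10 left-out cases and lost with arrays of the same day only (adjusted p = 0.0526) and with array weights (adjusted p = 0.126). That is 1 gene up and 2 down over all probe sets and 3 up and 2 down adjusted over the list alone. The median was 0.38 and the mean −0.38, and the set did not pass (camera, adjusted p = 0.974). The branched-chain aminotransferase BCAT2, the boron carriers BOR1 and NIP5;1 and the calcium exchanger CAX3 had no probe set of their own in the name table and were not analysed here.

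Genes known from sugar starvation and darkness also fell at 2 days. All 5 measured members lay lower, 4 of them past the threshold and 5 adjusted over the list alone, with a median of −1.58 (camera, adjusted p = 7.50e-05; adjusted p = 0.293 with an estimated correlation). Besides IVD and MCCA, which this list shares with the degradation list, ATL8 fell by 1.58 (adjusted p = 0.00900) and AKINBETA1, a subunit of the SnRK1 kinase, fell by 1.02 (adjusted p = 0.0219). The AKINBETA1 call was kept in 8 of 10 left-out cases and lost with arrays of the same day only (adjusted p = 0.0699) and with array weights (adjusted p = 0.121), as was that of ATL8 with array weights (adjusted p = 0.0765). In control plants of 4 days these 4 genes were likewise lower than in those of 2 days (IVD −2.25, MCCA −1.70, ATL8 −1.60 and AKINBETA1 −1.09). Of the 8 measured genes of wall loosening 3 rose (5 adjusted over the list alone). The xyloglucan endotransglucosylase XTH19 (AT4G30290) went from 85.0 ± 23.8 to 351 ± 233 (log2 change 1.72, SE 0.40, adjusted p = 0.0317). With each array left out this ran from 1.02 to 2.43, and the call was kept in 4 of 10 cases. It was lost with array weights (adjusted p = 0.116) and with arrays of the same day only (adjusted p = 0.0835). The expansin EXPA4 (AT2G39700) went from 144 ± 5.22 to 431 ± 77.5 (1.47, SE 0.17, adjusted p = 0.00285), and the expansin EXPA15 rose by 0.52 (adjusted p = 0.0480), though not with median centring (adjusted p = 0.0588). The EXPA15 call was kept in 2 of 10 left-out cases (0.38 to 0.67) and was also lost with a pseudocount of 64, without the filter, with either replicate block, with arrays of the same day only (adjusted p = 0.146) and with array weights (adjusted p = 0.193). In control plants of 4 days EXPA4 (1.87) and EXPA15 (1.22) were likewise higher than in those of 2 days. The median of the 8 was 0.65 (camera, adjusted p = 0.00196; adjusted p = 0.190 with an estimated correlation).

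Of the 3 measured auxin response genes, GH3.3 fell by 1.08 (adjusted p = 0.0428) and GH3.5 (WES1) fell by 0.82 (adjusted p = 0.0263); both encode enzymes that conjugate auxin. The GH3.3 call was kept in 3 of 10 left-out cases (−1.35 to −0.81) and lost with arrays of the same day only (adjusted p = 0.101) and with array weights (adjusted p = 0.228). That of GH3.5 was kept in 7 of 10 and lost with array weights (adjusted p = 0.200). All 3 fell adjusted over the list alone, with a median of −0.82 (camera, adjusted p = 0.0164; adjusted p = 0.320 with an estimated correlation). The set was no longer past the threshold without control 2 d replicate 1 (adjusted p = 0.0532) or replicate 2 (adjusted p = 0.0609). Among 3 root markers PYK10 rose by 0.73 (adjusted p = 0.0375), a call lost with median centring (adjusted p = 0.0607) and with the values as deposited (adjusted p = 0.0503). It was kept in 4 of 10 left-out cases and lost with either replicate block, with arrays of the same day only (adjusted p = 0.122) and with array weights (adjusted p = 0.187). All 3 rose adjusted over the list alone, with a median of 0.72 (camera, adjusted p = 0.0431; adjusted p = 0.432 with an estimated correlation). The set did not pass without control 2 d replicate 1 or 2 (adjusted p = 0.133 and 0.0987), boron-deficient 2 d replicate 2 (0.285) or boron-deficient 4 d replicate 1 or 2 (0.0532 and 0.0540), nor as deposited (0.0518) or with the replicate block (0.0566). Of 3 rapid stress transcription factors WRKY53 alone rose (0.93, adjusted p = 0.0155; 1 up adjusted over the list alone), with a list median of 0.58 (camera, adjusted p = 0.387). The WRKY53 call was lost without boron-deficient 2 d replicate 1, with arrays of the same day only (adjusted p = 0.0568) and with array weights (adjusted p = 0.0985).

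No gene of the other 5 lists passed over all probe sets at 2 days of boron deficiency. The 7 measured calcium genes had a median of −0.43 (camera, adjusted p = 0.394), with CML41 at −0.88 and CML37 at −0.58. The 3 photosynthesis genes had a median of −0.02 (adjusted p = 0.863), with RCA, the Rubisco activase, at −0.15 and LHCB4.1 at 0.04. The 3 oxidative stress genes had a median of 0.35 (adjusted p = 0.407), with glutathione reductase GR1 at 0.36 and AT2G21640 at 0.35. The 3 phenylpropanoid genes had a median of −0.03 and a mean of 0.17 (adjusted p = 0.871), with DFR at 0.77 and CCR2 at −0.23. The 3 genes of the abscisic acid, cold and dehydration list had a median of 0.24 (adjusted p = 0.358), with COR15B at 0.48 and COR15A at 0.24. Adjusted over the list alone, 1 gene of the last list rose, and 0 genes of the first 4 passed.

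The largest rise among genes with a probe set of their own was that of AT1G73600, from 109 ± 35.8 to 948 ± 321, which is 7.66-fold (log2 change 2.94, SE 0.28, adjusted p = 0.00146). It was also higher in control plants of 4 days than in those of 2 days (3.40). AT1G47400, the glutathione transferase GSTU20, AT5G54970, AT5G07030, AT4G26010, the tubulin TUB1, AT1G20380, AT5G42860 and AT1G67750 followed, with log2 changes between 2.18 and 1.89. The largest fall was that of AT1G09500, from 715 ± 149 to 85.6 ± 8.54 (log2 change −2.83, SE 0.26, adjusted p = 0.00146). AT1G19530 (−2.71), MGL, GAT1_2.1 (−2.50), AT1G71000 (−2.12), IVD, AT1G02660 (−1.97), MCCA, AT2G29500 (−1.72) and AT4G01870 (−1.71) completed the 10 largest falls. In all, 1454 of 17059 probe sets passed, 990 higher and 464 lower, and 410 of them differed at least 2-fold. With median centring 793 were higher and 562 lower, and 607 and 485 without control 2 d replicate 2. Leaving out 1 array in turn moved the count widely in both directions, and not all of the 36 named calls held. IVD, MCCA, MCCB, ETFQO, MGL and BCAT4 kept their direction in each case, at −2.30 to −1.80 for IVD and 1.59 to 1.67 for BCAT4. With only the groups compared the calls of IVD, MCCA, MCCB and ETFQO were lost, and those of MGL and BCAT4 were kept. The calls of AT1G20380 and AT1G02660 were kept in 2 of 10 left-out cases, that of AT4G01870 in 3 and that of AT4G26010 in 6, and all 4 were lost with arrays of the same day only and with array weights. In simulated data with the spread of the real groups 34.6% of the calls of this comparison were false. This share depends on how many changes were simulated, so it cannot be carried over to the 1454 calls. With weights for the spread of each group 206 probe sets and 16 of the 36 named calls passed, without IVD (adjusted p = 0.0566) and BCAT4 (adjusted p = 0.0515).

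**Figure D1:**
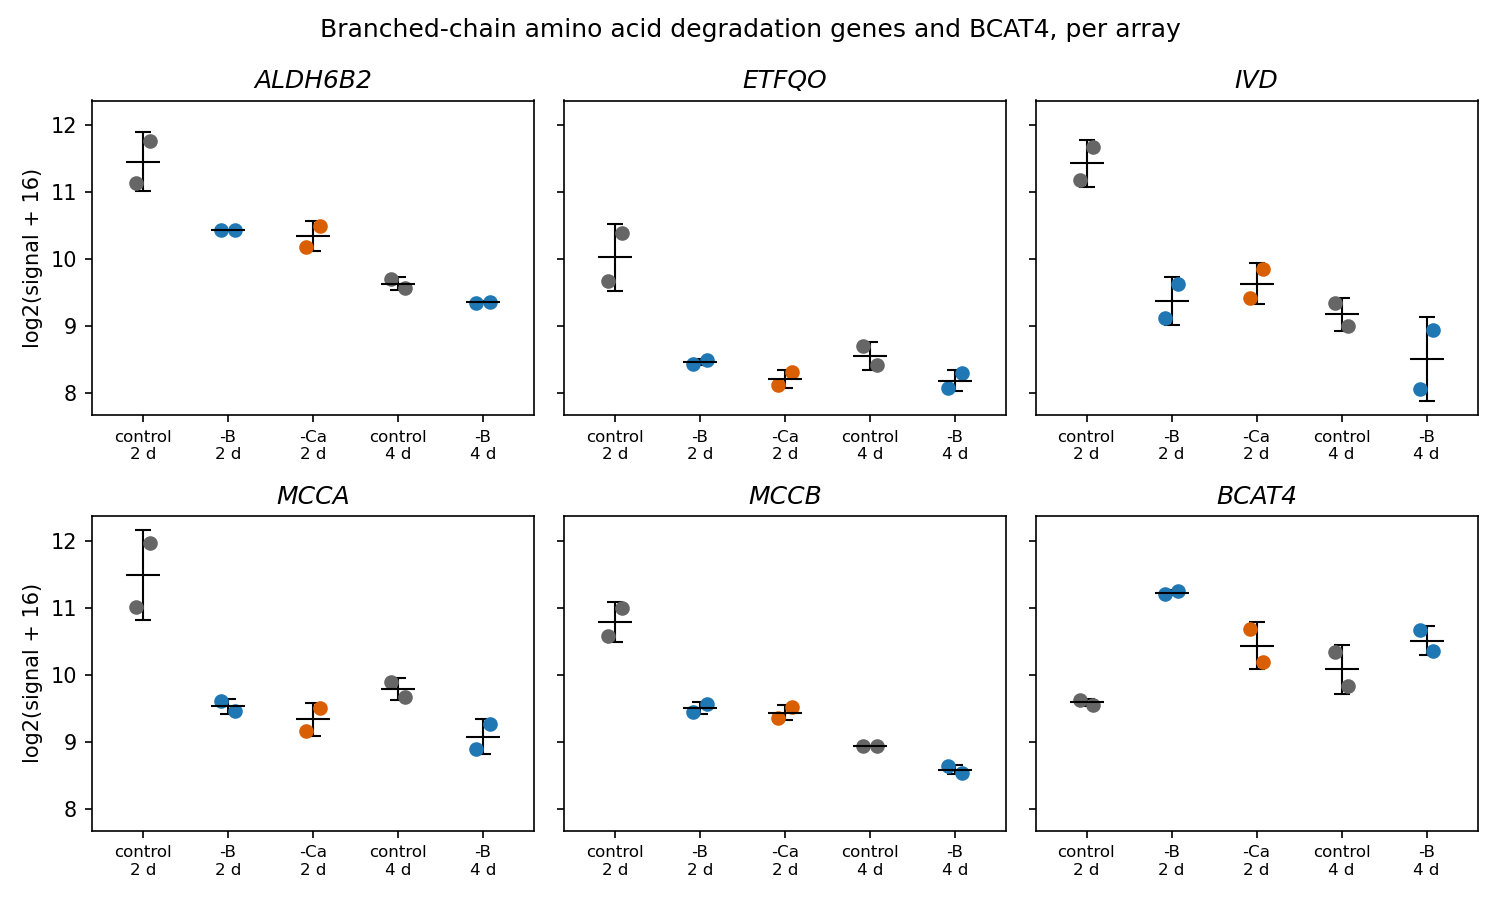
Log2(signal + 16) of 5 branched-chain amino acid degradation genes and BCAT4, with a dot per array, a dash at the mean of the 2 arrays of each group and bars of 1 SD. In the panel of IVD the boron-deficient and calcium-deficient plants of 2 days lie below their controls, and the control plants of 4 days lie below those of 2 days (log2 difference −2.25).

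The comparison at 4 days asked whether the answer to boron loss lasted. A single probe set passed: AT2G27420 rose from 159 ± 27.4 to 487 ± 3.45, which is 2.89-fold (log2 change 1.53, SE 0.15, adjusted p = 0.0297). The genes of amino acid breakdown did not pass, with signals of 567 ± 97.5 in control and 366 ± 160 in boron-deficient plants for IVD (log2 change −0.67, 95% confidence interval −1.36 to 0.03) and 870 ± 97.9 and 529 ± 98.8 for MCCA (−0.71, 95% confidence interval −1.34 to −0.08; adjusted p = 0.9996 for each). A fall of 2-fold lies within both intervals and was not excluded. BCAT4 stood at 1087 ± 277 and 1452 ± 218 (log2 change 0.43), and MGL at 455 ± 8.94 and 294 ± 31.3 (−0.61).

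As sets, 4 lists passed at 4 days with the preset correlation, and none with an estimated correlation. The degradation list had a median of −0.18 (camera, adjusted p = 0.00426; adjusted p = 0.190 with an estimated correlation), and without control 4 d replicate 1 it did not pass (adjusted p = 0.0603). The starvation list had a median of −0.67, with ATL8 at −0.76 (adjusted p = 0.000684; adjusted p = 0.320 with an estimated correlation). The auxin list had a median of −1.11, with the auxin-responsive IAA29 at −1.25 and GH3.3 at −1.11 (adjusted p = 8.35e-06; adjusted p = 0.190 with an estimated correlation), and all 3 members were lower adjusted over the list alone. The rapid stress factors had a median of 0.69, with WRKY53 at 0.70 and the zinc finger factor STZ (ZAT10) at 0.69 (adjusted p = 0.0122; adjusted p = 0.320 with an estimated correlation), and 1 member was higher adjusted over the list alone. With each array left out STZ ran from 0.20 to 1.19. This last set did not pass without control 4 d replicate 2 (adjusted p = 0.225) or boron-deficient 4 d replicate 2 (adjusted p = 0.390).

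The other 8 lists did not pass at 4 days, and no member of them or of the first 2 passed adjusted over the list alone. Their medians were −0.05 for branched-chain amino acid synthesis (adjusted p = 0.407; AHASS1 −0.37), −0.03 for wall loosening (0.978; mean 0.01; EXPA8 −0.55 and XTH19 0.46) and −0.06 for root markers (0.847; PYK10 −0.10 and EXPA7 −0.06). The photosynthesis genes had a median of 0.05 (adjusted p = 0.394; PRK 0.20 and LHCB4.1 0.05), the calcium genes −0.18 (0.847; CML38 −0.50 and CML37 0.46) and the oxidative stress genes −0.00 (0.978; mean 0.00; NDB2 −0.02 and AT2G21640 0.03). For phenylpropanoid genes the median was 0.52 (adjusted p = 0.142; DFR 0.53 and UF3GT 0.52), and for the abscisic acid, cold and dehydration genes 0.01 (0.871; mean −0.03; COR47 −0.14 and COR15B 0.04). With each array left out DFR ran from 0.067 to 0.996. The phenylpropanoid set passed without control 4 d replicate 1 (adjusted p = 0.0313) and without boron-deficient 4 d replicate 2 (adjusted p = 0.00688).

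Beyond AT2G27420, the lowest unadjusted p among genes that were higher belonged to AT1G04770 (log2 change 1.58, adjusted p = 0.0776), AT2G15020 (0.80, 0.322), AT5G54130 (0.71, 0.492) and TBL26 (1.30, 0.609). Among genes that were lower they belonged to IAA29 (adjusted p = 0.609), AT1G01240 (−0.69, 0.609), AT1G10140 (−0.82, 0.662), AT2G15960 (−1.02, 0.672) and CCL (−0.90, 0.808). By limma 1 probe set of 17059 passed, and 725 had an unadjusted p under 0.05. AT2G27420 did not pass without control 4 d replicate 1 or 2 (adjusted p = 0.106 and 0.508), boron-deficient 2 d replicate 1 or 2 (0.0622 and 0.0606), boron-deficient 4 d replicate 1 or 2 (0.671 and 0.135) or calcium-deficient replicate 1 or 2 (0.164 and 0.165); without boron-deficient 4 d replicate 2 another probe set passed, and in the other 7 cases 0 did. Simulated changes of 2-fold were recovered in 86.2% of cases at 4 days, in draws with 200 changed probe sets each. The adjusted threshold eases as more probe sets change, so this share cannot be carried over to a comparison with 1 call.

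Whether the answer to boron loss differed between the days was tested as the difference of the responses. How the arrays of each day were processed may not cancel in it. The expansin EXPA4 rose at 2 days, while at 4 days its signals were 568 ± 5.0 in control and 515 ± 18.1 in boron-deficient plants, and its responses differed by −1.60 on the log2 scale (SE 0.24, adjusted p = 0.0415). AT5G07030, AT1G67750, the thaumatin-like ATLP-1 (2 d log2 change 1.88) and DRT100 (1.496) had likewise higher 2 d responses. In the other direction stood AT1G09500, AT1G71000, AT2G20560, the co-chaperone Hop3 (2 d log2 change −1.45) and the asparaginase ASPGB1 (−1.14), with 4 d log2 changes of 0.30 for Hop3 and 0.45 for ASPGB1. The degradation genes had smaller changes at 4 days, but their differences did not pass: IVD 1.39 (adjusted p = 0.221), MCCA 1.24 (0.224), ETFQO 1.19 (0.152) and MCCB 0.93 (0.124). Nor did that of BCAT4 (−1.21, adjusted p = 0.136). As a set the 5 degradation genes had a median difference of 1.19 (fry, unadjusted p = 0.0225). Camera with an estimated correlation gave them an unadjusted p of 0.0680. These 5 were picked for falling at 2 days, which favours such a difference. In all 39 probe sets passed, 14 with a higher and 25 with a lower response at 4 days. The count was 428 and 104 without control 2 d replicates 1 and 2 (in the latter case 73 with a higher and 31 with a lower response), 2 and 0 without control 4 d replicates 1 and 2, 119 and 17 without boron-deficient 2 d replicates 1 and 2, 0 without boron-deficient 4 d replicate 2 and 10 without either calcium-deficient replicate; with limma's unadjusted p under 0.05, 1270 and 1380 probe sets were found where the count was 0. None of the 10 named calls held in every left-out case.

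Calcium-deficient plants of 2 days were compared with the same controls to ask which changes are not particular to boron; both elements bind to pectin in the wall. The same 5 degradation transcripts fell here too. MCCA fell to 635 ± 112, which is 4.44-fold (log2 change −2.15, adjusted p = 0.00166), IVD to 788 ± 169, which is 3.47-fold (−1.80, adjusted p = 0.00461), and ETFQO (−1.81, adjusted p = 0.00136), MCCB (−1.35, adjusted p = 0.00122) and ALDH6B2 (−1.11, adjusted p = 0.00505) fell as well. Of the 13 measured genes 5 fell and 0 rose (5 and 2 adjusted over the list alone), with a median of −0.23 (camera, adjusted p = 0.0311; adjusted p = 0.280 with an estimated correlation), and with the values as deposited the set did not pass (adjusted p = 0.0654). In the same plants the root marker PYK10 was higher (1.09) and the photosynthesis enzyme PRK lower (−0.69), and the controls are those whose 5 degradation genes stood above the controls of 4 days. The IVD call was lost without calcium-deficient replicate 1 (adjusted p = 0.0543). MGL fell to 409 ± 154 (−2.04, adjusted p = 0.00199) and AHASS1 fell by 0.82 (adjusted p = 0.0229), the 2 of 5 synthesis genes that passed in either count. The AHASS1 change ran from −1.06 to −0.56 with each array left out, and its call was lost with arrays of the same day only (adjusted p = 0.0649). The synthesis list had a median of 0.10 and a mean of −0.45 (camera, adjusted p = 0.634). BCAT4 rose to 1389 ± 339, which is 1.797-fold (0.85, adjusted p = 0.0206). With each array left out this ran from 0.60 to 1.09. Its call was lost without control 2 d replicate 2 or calcium-deficient replicate 1, and with array weights (adjusted p = 0.0841).

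Starvation genes fell under calcium loss as well, 4 of 5 over all probe sets and 5 adjusted over the list alone, with ATL8 at −1.39 (adjusted p = 0.00639) and AKINBETA1 at −0.83 (adjusted p = 0.0227). The AKINBETA1 call was kept in 8 of 10 left-out cases and lost with arrays of the same day only (adjusted p = 0.0611) and with array weights (adjusted p = 0.0524). The controls are those in which these genes stood above the controls of 4 days. Their median was −1.39 (camera, adjusted p = 0.00160; adjusted p = 0.320 with an estimated correlation). Of the wall loosening genes 4 rose in either count: XTH19 to 381 ± 57.9 (log2 change 1.99, adjusted p = 0.00871), EXPA4 to 347 ± 82.2 (1.16, adjusted p = 0.00269), the pectin methylesterase PME41 (ATPMEPCRB; 0.82, adjusted p = 0.0410) and XTH20 (0.66, adjusted p = 0.0225). The PME41 call was kept in 5 of 10 left-out cases (0.52 to 1.12). It was lost with either replicate block, with arrays of the same day only (adjusted p = 0.0610) and with array weights (adjusted p = 0.0993). That of XTH20 was kept in 7 of 10 and lost with arrays of the same day only (adjusted p = 0.0616). Their median was 0.46 (camera, adjusted p = 0.0408; adjusted p = 0.295 with an estimated correlation), and the set did not pass without control 2 d replicate 1 (adjusted p = 0.114) or replicate 2 (adjusted p = 0.0609). Among the calcium genes the calmodulin-like CML47 (AT3G47480; 1.61, adjusted p = 0.0190) and CML45 (AT5G39670; 0.94, adjusted p = 0.0117) rose. With each array left out CML47 ran from 1.12 to 2.09 and CML45 from 0.66 to 1.21. The CML47 call was lost with arrays of the same day only (adjusted p = 0.0538). CML30 fell by 0.69 (adjusted p = 0.0463), a call kept in 2 of 10 left-out cases and lost without the filter, with the replicate block, with arrays of the same day only and with array weights. That is 2 up and 1 down in either count, with a median of 0.26 (camera, adjusted p = 0.407).

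Among the smaller lists, the photosynthesis enzymes PRK (−0.69, adjusted p = 0.00309) and RCA (−0.49, adjusted p = 0.00894) fell, 2 of 3 in either count, with a median of −0.49 (camera, adjusted p = 0.134). PYK10 rose by 1.09 (adjusted p = 0.00379), 1 of 3 root markers in either count, with a median of 0.34 (adjusted p = 0.216). NDB2 (0.70, adjusted p = 0.0401), a mitochondrial NADH dehydrogenase, and GR1 (0.63, adjusted p = 0.0105) rose, 2 of 3 oxidative stress genes in either count, with a median of 0.63 (adjusted p = 0.203). The NDB2 call was kept in 2 of 10 left-out cases and lost with arrays of the same day only (adjusted p = 0.0998) and with array weights (adjusted p = 0.0622). CCR2, a cinnamoyl-CoA reductase, rose by 0.68 (adjusted p = 0.0226), 1 of 3 phenylpropanoid genes (2 adjusted over the list alone), with a median of 0.68 (adjusted p = 0.296). The CCR2 call was kept in 8 of 10 left-out cases and lost with arrays of the same day only (adjusted p = 0.0700) and with array weights (adjusted p = 0.0558), and that of RCA was lost with arrays of the same day only (adjusted p = 0.0545). WRKY53 rose by 0.97 (adjusted p = 0.00542), 1 of 3 rapid stress factors in either count, with a median of 0.30 (adjusted p = 0.394). No member of the auxin list (median −0.48, adjusted p = 0.533; GH3.5 −0.49 and IAA29 −0.48) or of the abscisic acid, cold and dehydration list (median 0.09, adjusted p = 0.875; COR15B 0.16 and COR47 −0.11) passed in either count. From lists with fewer than 3 measured genes, the defensin PDF1.2 rose by 1.79 (adjusted p = 0.00452) and BOR3 (AT3G06450), of the borate exporter family, by 0.72 (adjusted p = 0.00765).

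The largest rises under calcium loss were those of AT3G28510, from 47.8 ± 20.1 to 867 ± 122 or 14.1-fold (log2 change 3.82, SE 0.44, adjusted p = 0.00122), and AT2G44240, from 76.2 ± 2.71 to 1062 ± 20.3 or 11.7-fold (3.55, SE 0.40, adjusted p = 0.00121). AT4G33720 (3.29), AT5G23840 (2.77), AT5G03350 (2.70), AT3G57950 (2.64), AT1G20380 (2.63), AT1G43910 (2.62), AT1G55210 (2.48) and AT3G53980 (2.44) followed. AT1G66100 fell most (−3.06, SE 0.53, adjusted p = 0.00471), before AT1G09500 (−2.51), AT1G62510 (−2.37), GAT1_2.1 (−2.29), AT1G19530 (−2.17), AT1G71000 (−2.16), MCCA, AT1G54740 (−2.12), AT5G62360 (−2.10) and AT1G02660 (−2.08). In all 3706 probe sets passed, 2012 higher and 1694 lower, and 895 of them differed at least 2-fold. More were lower than higher with the values as deposited (1681 higher and 1932 lower), with median centring (1688 and 1997) and without control 2 d replicate 2 (1593 and 1700). Fewer probe sets passed without either calcium-deficient replicate, and not all of the 44 named calls held with each array left out. In simulated data with the spread of the real groups 14.6% of the calls of this comparison were false. This share too depends on how many changes were simulated and cannot be carried over to the 3706 calls.

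Genes encoded in the plastid genome, a set formed after the data had been seen, fell in calcium-deficient plants. Of 69 measured genes 42 fell and 0 rose (49 and 0 adjusted over the list alone), and all 69 had a negative log2 change, with a median of −0.61 and quartiles of −0.94 and −0.39. The photosystem genes psbD (−1.29) and psaC (−1.20), ndhE (−1.42) of the NADH dehydrogenase-like complex, accD (−1.19) of fatty acid synthesis, the photosystem gene psbA (−1.08) and rbcL (−0.74), the large subunit of Rubisco, were among those that fell. With the values as deposited and with median centring the median was −0.71 and −0.70. The set lay lower than the other genes (camera, adjusted p = 1.36e-16), but not with its correlation estimated (adjusted p = 0.750 with an estimated correlation). By fry it passed in calcium-deficient plants (adjusted p = 0.0167). In boron-deficient plants its median was −0.09 at 2 days, where 1 gene rose, and 0.14 at 4 days, where none passed (camera, adjusted p = 1.78e-07; adjusted p = 0.750 with an estimated correlation). With each array left out these medians ran from −0.10 to −0.0061 at 2 days and from 0.023 to 0.24 at 4 days.

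**Figure D2:**
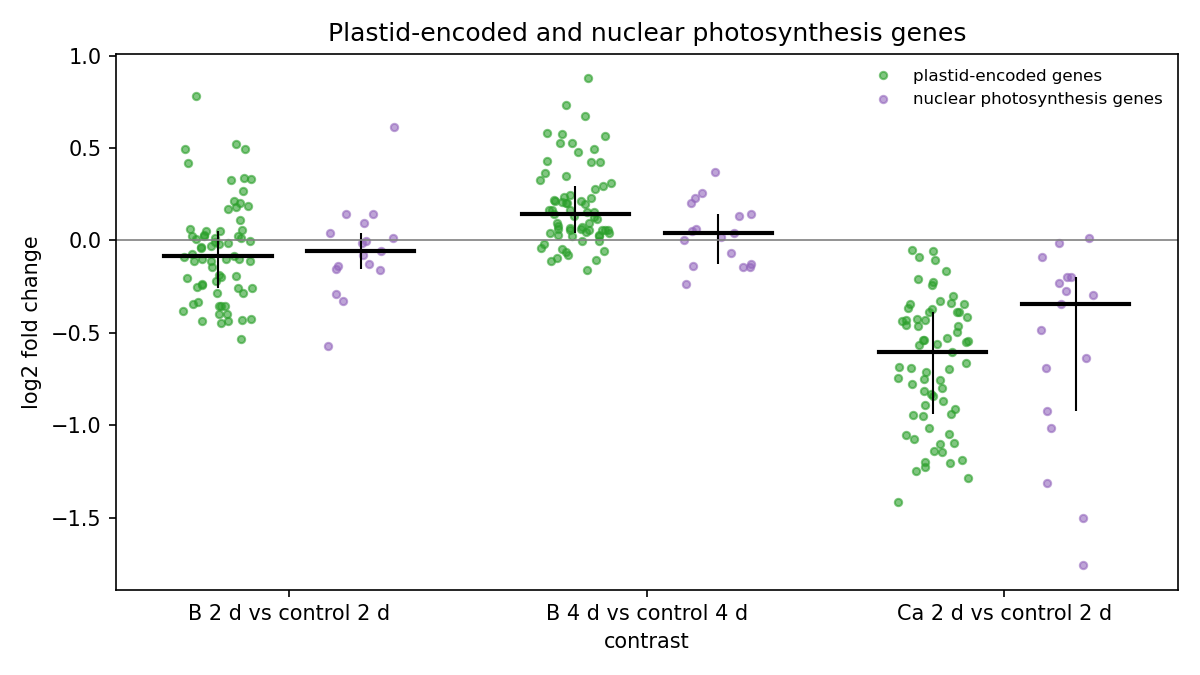
Log2 changes (y axis) of the 69 plastid-encoded genes and of 17 nuclear photosynthesis genes in the 3 deficiency comparisons, with a dot per gene, a thick line at the median and a thin line between the quartiles. All 69 plastid-encoded genes lie below 0 in calcium-deficient plants.

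Boron-deficient and calcium-deficient plants of 2 days were compared directly to ask where the deficiencies part. Calcium-deficient plants had far higher AT3G28510 (log2 difference, boron over calcium, −3.42, adjusted p = 0.00410), AT2G44240 (−3.01, adjusted p = 0.00475), AT1G21520 (−2.79, adjusted p = 0.00498), AT4G05030 (−2.75, SE 0.13, adjusted p = 3.92e-05) and CHI (AT2G43570; −2.31, adjusted p = 0.0118). Boron-deficient plants had higher AT5G62360 (2.27, adjusted p = 0.00696), AT1G73600 (1.91, adjusted p = 0.00594), AT4G21870 (1.60, adjusted p = 0.00521), AT2G10940 (1.59, adjusted p = 0.00384) and AT1G75960 (1.56, adjusted p = 0.0283). The difference of AT1G75960 ran from 0.87 to 2.26 with each array left out. Its call and that of CHI were lost with arrays of the same day only (adjusted p = 0.0921 and 0.0534). BCAT4 was higher in boron-deficient plants (0.79, adjusted p = 0.0436), as was UGT74C1 (AT2G31790; 0.63, adjusted p = 0.0241). GH3.3 (−1.40, adjusted p = 0.0150) and the calmodulin-like CML47 (AT3G47480; −1.53, adjusted p = 0.0379) and CML45 (AT5G39670; −1.05, adjusted p = 0.0143) were lower there. The 5 degradation genes had a median difference of 0.09, and none of them passed. In all 1784 probe sets passed, 978 higher and 806 lower with boron deficiency. The count was 1140 and 1137 without control 4 d replicates 1 and 2, 361 without boron-deficient 2 d replicate 1, and 215 (100 higher and 115 lower) and 110 (43 and 67) without calcium-deficient replicates 1 and 2; of the 5 largest differences in each direction 3 held in every left-out case. The calls of GH3.3, UGT74C1, CML45, BCAT4 and CML47 were kept in 8, 7, 7, 4 and 3 of 10 left-out cases. With arrays of the same day only that of CML45 was kept (adjusted p = 0.0491) and the other 4 were lost, and that of BCAT4 was also lost without the filter and with array weights (adjusted p = 0.0762), that of CML47 with the replicate block.

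How far the responses are shared was asked from the log2 changes over all 17059 probe sets, which are not independent replicates. IVD, MCCA, MCCB, ETFQO, ALDH6B2, MGL, ATL8, AT1G09500 and AT1G71000 fell in both deficiencies at 2 days, and EXPA4, XTH19, WRKY53, PYK10, BCAT4 and AT1G20380 rose in both. The boron calls of AT1G20380, XTH19, PYK10 and WRKY53 were kept in 2, 4, 4 and 9 of 10 left-out cases. With array weights BCAT4 lost its call in both comparisons (adjusted p = 0.0515 for boron and 0.0841 for calcium). Both comparisons called 623 probe sets higher and 272 lower, where independent lists of these sizes give 117 and 46.1, and 15 had opposite directions. Pearson's correlation across probe sets was 0.640 (Spearman 0.601) and 93.3% of the boron calls had the same sign under calcium loss. Both comparisons use the same 2 control arrays. Unchanged groups simulated against shared controls gave a correlation of 0.657 (0.637 to 0.675 in 100 draws) and fewer than 1 shared call per draw. No probe set was changed in this simulation, so its few calls follow from the setup. They are no reference for the 623 and 272 shared calls. The simulated 98.5% of equal signs covers only draws with boron calls and is not comparable with the 93.3%. Noise was drawn for each probe set alone, so deviations that probe sets share in the control arrays are missing from the simulation. The covariance was 0.132 against 0.0375 in the simulation, a difference of 0.0946. The controls cannot be split with 2 arrays on each side, so part of the excess may come from the shared controls. Boron responses at 2 and 4 days share no arrays and correlated with 0.319 (Spearman 0.278), with 67.5% of the 2 d calls keeping their sign and no probe set called in both. Calcium at 2 days and boron at 4 days correlated with 0.0357 (Spearman 0.0163).

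Control plants of 4 days were compared with those of 2 days to show how the background moved between the days, which also differ in plant age and in how the arrays were processed; these cannot be told apart. IVD fell by 2.25 on the log2 scale (adjusted p = 0.000562), and MCCB (−1.85, adjusted p = 3.33e-05), ALDH6B2 (−1.82), MCCA (−1.70) and ETFQO (−1.47) fell with it. AT5G62360 (−4.47), CML38 (−1.94), MGL (−1.84), CML41 (−1.74), ATL8 (−1.60), XTH20 (−1.58) and AKINBETA1 (−1.09) fell too. AT1G73600 rose by 3.40, the anthocyanin enzyme DFR by 2.30, EXPA4 by 1.87, PYK10 by 1.46, IAA29 by 1.34 and EXPA15 by 1.22. BCAT4 did not pass (0.50, adjusted p = 0.0950). In all 6118 probe sets passed, 3216 higher and 2902 lower, and 3006 higher and 3478 lower with median centring. The count was 3622 and 3406 without control 4 d replicates 1 and 2. With the values as deposited the median of all probe sets lay 0.89 higher at 4 days and 14775 passed, 14324 of them higher, so these changes are given relative to the normalized distribution.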

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

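The tests of a smaller shoot share, of the state of the control plants, of the spread between 2 d replicates and of the changes shared by pairs of arrays were chosen only after the result was seen; the tests of a single control array and of the pooled spread were set down before theirs.

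The boron response differed between 4 and 2 days in 39 probe sets by the interaction test. Higher at 4 days relative to 2 days were AT1G09500 (log2 difference 2.86, adjusted p = 0.0242), AT1G71000 (2.15, 0.0152), AT2G20560 (1.86, 0.0304), the co-chaperone Hop3 (1.755, 0.0304) and the asparaginase ASPGB1 (1.59, 0.0433). Lower were AT5G07030 (−2.17, 0.0242), ATLP-1 (−1.93, 0.0346), AT1G67750 (−1.70, 0.0346), DRT100 (−1.64, 0.0272) and EXPA4 (−1.60, 0.0415). With median centring EXPA4 and ASPGB1 did not pass (adjusted p = 0.0510 for each), nor did ASPGB1 with the values as deposited (0.0579). With array weights per group the calls of Hop3 (adjusted p = 0.0477) and AT1G71000 (0.00907) were kept among the 10. The replicate block ended 7 of the 10 calls, those of Hop3, ATLP-1, DRT100, ASPGB1, AT2G20560, AT1G09500 and EXPA4.

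Boron deficiency gave 1454 calls at 2 days and 1 at 4 days. Changes at 4 days as large as at 2 days, hidden by a spread pooled over both days, are argued against. The log2 changes that 2 separate pairs of arrays shared, a value without the pooled spread, were compared over both pairings. Their SD was at most 0.119 at 4 days and at least 0.285 at 2 days, with quantile normalization and as deposited. Median centring cannot change this value. Whether the pooled spread hides smaller changes at 4 days cannot be told apart from their absence. The 4 arrays of 4 days alone gave 0 calls by limma, but the 4 arrays of boron at 2 days alone gave 44, so a fit of 4 arrays does not decide it. The probe sets at an unadjusted p under 0.05 were 725 at 4 days in the fit of all arrays, 1644 in the 4 arrays alone and 1779 with array weights, where calls were 3. A spread between 2 d replicates that the pooled fit understates was measured, with a root mean square SD of 0.27 and 0.25 in the control and boron-deficient arrays of 2 days against 0.14 and 0.16 at 4 days. With array weights for it 206 calls were left at 2 days and 3 at 4 days (2669 and 1779 at an unadjusted p under 0.05), so it may account for many of the calls but not for the whole contrast between the days. A weaker response at 4 days, a difference the design names, stays open beside the processing of the arrays by day.

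The degradation genes IVD, MCCA, MCCB, ETFQO and ALDH6B2 were lower in both deficiencies at 2 days, with medians of −1.56 and −1.80. These 5 were picked for passing in both contrasts, and the medians of all 13 measured degradation genes were −0.26 and −0.23. With either control array of 2 days left out the median of the 5 was at most −1.197 in either contrast. For these 5 genes the fall did not rest on a single control array, though picking them favours this. The median of the 17 nuclear photosynthesis genes lay above that of the 5 genes by at least 1.45 in both contrasts. A gap from genes picked for falling is favoured in advance, so a smaller share of shoot tissue stays open. A state of the control plants of 2 days that both contrasts share cannot be told apart from a response to the deficiencies: the same 5 genes were higher in these controls than in the controls of 4 days (−1.82), and at 4 days the median of −0.37 (fry, unadjusted p = 0.114) lay between what either explanation predicts. The whole list of 13 passed by fry at 4 days (adjusted p = 0.0261), with a median of −0.18. A response of leucine and valine breakdown that both deficiencies share may be present, and it is left as an untested hypothesis.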

How the results depend on the processing

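The tests with arrays of the same day only, with array weights per group and with crossed block numbers were chosen only after the result was seen. Of the 101 gene calls 99 stayed with a pseudocount of 64, 98 as deposited, 96 with median centring and 101 without the intensity trend, all in their direction. With a pseudocount of 1, 97 of those tested stayed in their direction and 1 was lost. Array weights kept 67, and arrays of the same day only kept 66 of those tested. Boron at 2 days gave 1454 calls, and 44 with only the groups compared, 456 with the same day only, 410 with the 2-fold threshold and 206 with array weights. Calcium gave 3706, and 2276, 1905 and 895 under the first 3 of these. Boron against calcium gave 1784, and 627, 442 and 408 under the same 3. The difference of boron responses gave 39, and 10 with only the groups compared and 11 with array weights. Controls at 4 against 2 days gave 6118, and 1770 with the 2-fold threshold and 14775 as deposited, where the shift of 0.89 between the days remains. A stricter threshold lowers these counts by construction. For boron at 2 days with array weights, the larger spread between 2 d replicates given above may account for part of the fall. Beyond this, why the counts were lower with fewer arrays or with array weights was not tested. Boron at 4 days gave 1 call by limma (725 probe sets at an unadjusted p under 0.05), 0 with a pseudocount of 1 (723), the 50th percentile filter (538), only the groups compared (1644) or the same day only (1644), 2 with median centring and 3 with array weights; the cause was not tested. With each array left out in turn the counts ran from 738 to 2784 for boron at 2 days, 0 to 1 at 4 days (at 0, 258 to 929 at an unadjusted p under 0.05), 996 to 4221 for calcium, 110 to 2495 for boron against calcium, 0 to 428 for the difference of responses and 3406 to 6522 for the controls; a lone array was taken to vary like the other groups. Of the list tests 12 passed and 0 with an estimated correlation, and 9 to 12 with each array left out. The degradation list had an adjusted p of 0.222, 0.190 and 0.280 with an estimated correlation in the boron 2 d, boron 4 d and calcium contrasts, of 0.0654 as deposited under calcium, and of 0.00968 to 0.0295, 0.00100 to 0.0603 and 0.0212 to 0.0436 with each array left out. Without the filter the correlation behind the overlap of the B 2 d and Ca 2 d responses was 0.653 and that behind the overlap of the B 2 d and B 4 d responses 0.30; the cause was not tested. No called gene changed direction. Values that had not passed did: LHCB4.1 at 2 d of boron went to −0.00266 with median centring, and with each array left out the log2 changes ran from −0.0296 to 0.12 for LHCB4.1 and −0.00055 to 0.48 for COR15A (boron 2 d), −0.00967 to 1.04 for UF3GT, −0.30 to 1.2 for CML37, −0.0916 to 0.0414 for NDB2, −0.13 to 0.00740 for EXPA7 and −0.0508 to 0.11 for AT2G21640 (boron 4 d), and −0.31 to 0.0907 for COR47 and −0.0593 to 0.38 for COR15B (calcium). Replicate numbers are not stated to pair arrays: deviations of arrays with the same number correlated with −0.25 to 0.23 across groups, and with −0.21 between control and boron-deficient plants at 2 days. With a replicate block the counts were 1288 for boron at 2 days, 0 at 4 days (794 at an unadjusted p under 0.05), 3431 for calcium, 1674 for boron against calcium, 15 for the difference of responses and 5880 for the controls, and with a block from the numbers in the descriptions boron gave 952 at 2 days (728 shared with the 1454) and 0 at 4 days (1071), and CML37 at 2 d stood at 0.0426. The block ended 16 of the 101 gene calls and 2 list calls and added that of GH3.5 under calcium; crossed numbers in the block gave 1571 calls for boron at 2 days (1354 shared). The filter at the 25th percentile limits what is known of transcripts near background: 5687 probe sets were not tested.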

Other observations

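The tests of gene families, of plastid-encoded genes, of the shoot share and of the height of the control arrays were chosen only after the result was seen; the test of quantile normalization was set down before its result.

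Of 20 measured serine carboxypeptidase-like genes 4 rose and 0 fell in boron-deficient plants of 2 days (11 and 0 adjusted over the list alone): scpl35 (log2 change 1.54), scpl29 (0.87), SCPL27 (0.65) and SCPL45 (0.63). Of the 20, 13 had a positive log2 change, with a median of 0.35, and of 0.34 as deposited and 0.30 with median centring (camera, adjusted p = 0.0157; adjusted p = 0.750 with an estimated correlation). In calcium-deficient plants 7 members rose, scpl16 (1.73), scpl35 (1.52) and scpl46 (1.33) among them, and SCPL34 fell by 0.86, with a median of 0.12, and of 0.06 in both of those settings (camera, adjusted p = 0.153). Glutathione transferases of the tau class parted in calcium-deficient plants: GSTU26 (2.22), GSTU20 (1.34), GSTU27 (0.998), GSTU28 (0.65) and GSTU22 (0.44) rose and GSTU18 fell by 0.76, with a median of 0.54 (camera, adjusted p = 0.149) and of 0.46 and 0.47 as deposited and with median centring, where 4 rose. Beta-glucosidases parted under boron loss, where BGLU40 (1.099) and BGLU44 (0.68) rose and BGLU46 (−1.52) and BGLU45 (−0.84) fell; under calcium loss BGLU25 (1.92), BGLU40 (1.26), BGLU15 (1.15) and BGLU42 (0.50) rose (camera, adjusted p = 0.175).

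Plastid-encoded transcripts were lower in calcium-deficient plants, with a median of −0.61 over 69 genes. Quantile normalization as the source is argued against, since the median stayed at −0.70 or lower with median centring and with the values as deposited. Control arrays that stand high are argued against, since the genes lay above the calcium-deficient plants in boron-deficient plants of the same day too, by a median of 0.66. A smaller share of shoot tissue stays open: 17 nuclear photosynthesis genes had a median of −0.34, with 8 lower and the Calvin cycle enzyme SBPASE at −1.31, and the difference from the plastid-encoded genes, 0.26, had a permutation p of 0.0849 over genes, two-sided, in 100000 resamples. A lower level of plastid transcripts for each cell may add to it, and was not tested.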
